A study of Mus musculus with 6 samples.

How the data were processed

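Brain myeloid cells of mice were profiled by Drop-seq, a droplet method that tags each captured transcript with a cell barcode and a unique molecular identifier (UMI) and counts its 3′ end. Per the labels' protocols, perfused brains were digested with a papain kit, mononuclear cells were taken from a Percoll gradient, and Cd11b-positive cells were enriched on magnetic columns. Cd11b is carried by myeloid cells and by NK cells, so this enrichment sets in part which cell classes could be seen and in what shares. Per the labels, the libraries of replicate 1 were sequenced on a HiSeq 2500, and those of replicate 2 and of both Cx3cr1 genotypes on a NextSeq 500.

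The authors deposited 1 table of raw UMI counts per library, genes by barcodes, with 1000 barcodes in each. The unit was read from the values, which are whole numbers with a different total in every library. Per the submitters' processing notes, STAR and Seurat were used and mm10 was the genome build. Their versions, settings and roles, the gene annotation and the way the 1000 barcodes were chosen are not given in the sources used here. Coordinates come from the GENCODE annotation of GRCm38, the assembly also called mm10, and cover the whole annotated gene.

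Groups were taken from the sample labels. The names of the deposited tables give the opposite group for all 4 libraries of unmodified mice, in both replicates. The labels were followed throughout, and these libraries are called by their labels. No library repeated another: at most 1 barcode was shared between any pair of libraries.

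Barcodes with at least 400 detected genes and under 10% mitochondrial UMIs were kept. Scrublet scores, as implemented in scanpy 1.11.5, ranked the barcodes of each library as possible doublets, and the top 5% were removed. The automatic Scrublet threshold was not used, because it marked a large part of the smallest library. Counts were scaled per cell and log-transformed, 2000 variable genes were chosen across libraries, and 30 principal components and 15 neighbours were passed to Leiden clustering (igraph 0.11.9) at resolution 1. No batch correction was applied. A cluster was given a class name, with the ending "-like", from 16 marker lists fixed before the data were examined. At least 3 markers had to reach 50 CPM in 5% of its cells, its mean marker level had to reach 0.3 of that in the highest cluster, and a marker had to stand among its 50 leading genes. Leading genes were ranked by fold against the other cells with 20 CPM added. A cluster with 90% of its cells in a single library could be named against the rest of that library, at a median log2 marker ratio of 1.5 or more. Clusters whose best classes lay within 0.1 of each other stayed unnamed. The mitochondrial limit, the doublet rule and the marker score limits were set after the distributions and clusters had been seen, and the closing section gives the effect of other settings.

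Cells are not replicates. UMI counts were therefore summed per library, over microglia-like cells and over all kept cells. Metastasis was compared with naive, 2 libraries in each group, with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Gene lists, 16 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Macrophage-like cells were to be compared only with at least 20 cells in each of the 4 libraries, which was not met. The edgeR p-values measure only the spread between these libraries, since the labels do not say how the brains were handled together or apart. Camera sets the changes of a list's genes against those of the other genes. With a preset correlation its p-values do not measure whether the libraries of a group repeat each other.

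The Cx3cr1-null and Cx3cr1-heterozygous groups have 1 library each, so their comparison has no test and no replicate check. Log2 ratios of CPM were computed for genes with at least 50 UMIs over both libraries. Exact 95% intervals of ratios, levels (Poisson) and shares (Clopper-Pearson) cover counting error only. For a count of 0 a floor of 3 counts was used. The median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The interval of a list's median came from 2000 simulated draws of its members' counts. Shares of cells with a UMI were compared after each cell was thinned to 800 UMIs, and shallower cells were left out. Shares of cell classes were compared with an exact two-sided permutation test, whose smallest possible p with 2 libraries against 2 is 0.333.

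Named genes were chosen by rules fixed before the data were examined. They were Cx3cr1 and Cxcl10 in every library, up to 10 genes per direction past the threshold between metastasis and naive with an average log2 CPM of at least 5 and the same sign in both replicates, the 4 members of each list with the highest mean level, and up to 8 genes per direction with the largest null over heterozygous ratio whose counting interval left out equality. Names that start with Gm and a digit, end in Rik or start with mt- were left out of the fold-based parts. The 5 per direction planned for macrophage-like cells were not needed. A gene named outside these rules is marked as chosen after its values were seen. Single values of 2 list members are not reported here, although the list results include them.

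The edgeR comparison in microglia-like cells, the camera step and the null over heterozygous intervals were tested on simulated counts. These were drawn from the real means and library sizes, with 200 genes changed for the edgeR comparison and for the intervals. In the microglia-like comparison of metastasis with naive, 5015 simulated genes were tested at a dispersion of 0.05. The test recovered 9 of the 89 tested genes changed by log2 1, which is 10.1%, and 77 of 89, or 86.5%, of those changed by log2 2, with 7 false calls. The camera step, with the type I interferon list raised by log2 1 among 5371 genes, gave that list an adjusted p of 3.64e-12 and called 0 of the other 15 lists. In both simulations the dispersion was set and not estimated from these libraries, and genes were drawn independently. Changed genes were shifted alike in both metastasis libraries. These tests therefore do not show how the steps perform with correlated genes, a larger spread or replicates that disagree. For null over heterozygous, 95.4% of the counting intervals of 4329 genes held the true ratio, and intervals left out equality for 88% of the genes changed by log2 1, for 98% of those changed by log2 2 and for 4.55% of unchanged genes.

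The replicate number pairs the libraries because it is the sequencer in the labels. The deviations of same-numbered libraries from their group means had a correlation across genes of −0.14 in microglia-like cells and −0.41 over all cells, so they did not deviate together. Fits with the replicate number as a block were run as alternatives. The others were DESeq2 1.42.0, RLE size factors, no low-count filter, each library left out, other limits on genes (800, 200 and none) and mitochondrial share (25%), doublets kept, coarser clustering (resolution 0.5), clustering after centring each library, thinned cells, TMM-scaled ratios and a minimum of 20 UMIs. Estimated inter-gene correlation, fry and list membership were varied for the lists. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.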

Results

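Single-cell UMI counts were obtained from Cd11b-enriched brain cells of female C57BL/6 mice aged 2 to 3 months. Brains with metastases were taken 2 to 3 weeks after cardiac injection of E0771 cells, a mouse mammary carcinoma line. The naive group and the metastasis group had 2 libraries each, every one from 1 brain. Metastasis-bearing Cx3cr1-heterozygous and Cx3cr1-null mice gave 1 library each, from 2 pooled brains. Total UMIs were 1222347 in naive 1, 2667099 in metastasis 1, 1622472 in naive 2, 491621 in metastasis 2, 2376501 in the heterozygous and 1764092 in the null library. After filtering, these libraries kept 399, 940, 171, 76, 238 and 152 cells in the same order. The median mitochondrial share per deposited barcode was 8.64% in naive 1, 2.96% in metastasis 1 and 3.60% in metastasis 2. It was 19.3% in naive 2, 20.3% in the heterozygous and 19.4% in the null library. The names of the deposited tables give the opposite group from the sample labels for all 4 libraries of unmodified mice, and the labels are used here.

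Cx3cr1, which encodes the fractalkine receptor of microglia and monocytes, was far lower in microglia-like cells of the null library. It stood at 55.1 CPM there (34.9 to 82.7, 23 UMIs) and at 1272 CPM in the heterozygous library (1194 to 1354, 993 UMIs). The log2 ratio was −4.53 (−5.19 to −3.93). Microglia-like cells of unmodified mice held 4457 CPM in naive 1, 960 CPM in metastasis 1, 2258 CPM in naive 2 and 4395 CPM in metastasis 2. Metastasis 1 thus lay below both naive libraries and metastasis 2 between them, and the fitted log2 change of −0.44 (SE 0.79) did not pass (edgeR quasi-likelihood, adjusted p = 0.995). The gene lies on chromosome 9 at 119901616 to 120069879 on the minus strand (mm10). The labels do not describe the altered allele, and 3′ counts can come from outside the altered part, so the level checks the null label only as far as the mutation removes this transcript.

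**Figure D1:**
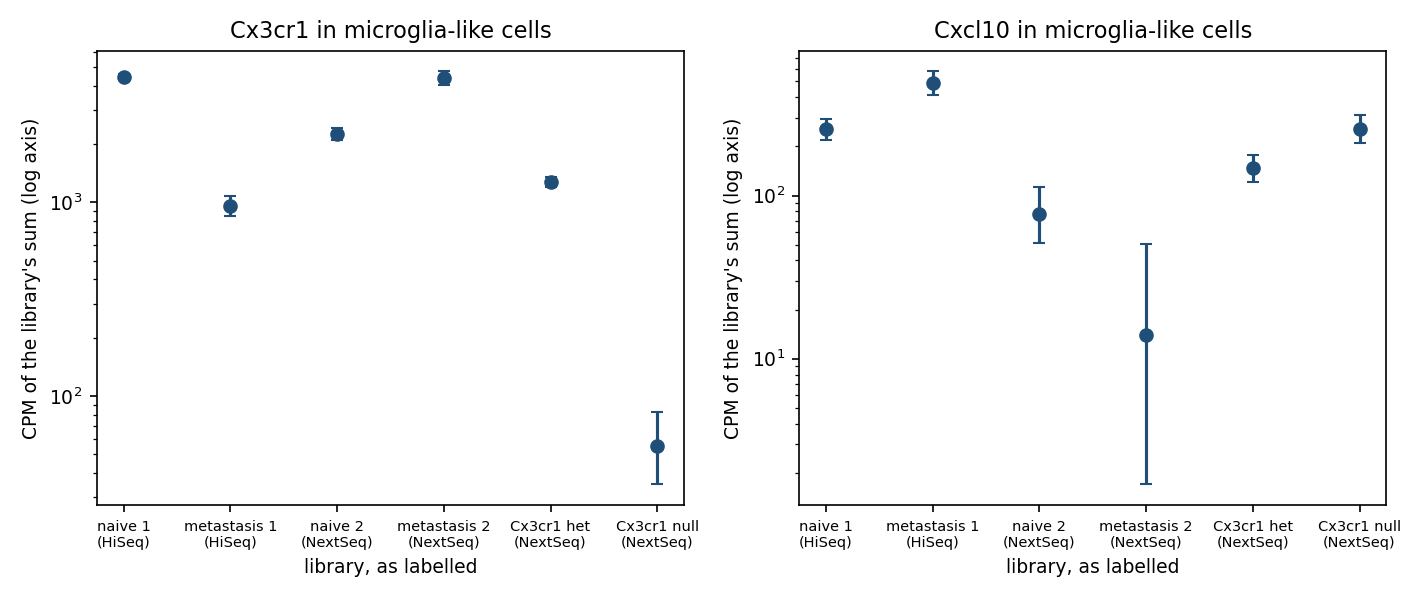
Cx3cr1 and Cxcl10 in microglia-like cells of each library, in CPM of the library's sum on log axes, with exact 95% counting intervals. Cx3cr1 stands at 1272 CPM in the heterozygous and at 55.1 CPM in the null library, and Cxcl10 ranges from 14.0 CPM in metastasis 2 to 490 CPM in metastasis 1.

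The suspensions of naive and metastasis-bearing brains differed mainly in a single library. Microglia-like cells, named by markers such as P2ry12, Tmem119 and Sall1, made up 92.5% (89.4 to 94.9) of naive 1, 69.6% (62.1 to 76.4) of naive 2 and 94.7% (87.1 to 98.5) of metastasis 2, but 17.0% (14.7 to 19.6) of metastasis 1. They made up 76.9% of the heterozygous and 80.9% of the null library. Of the 160 microglia-like cells of metastasis 1, 156 lay in a cluster named only against the rest of that library. The share of metastasis 1 thus rests on a different naming rule. Macrophage-like cells made up 20.6% of metastasis 1 (194 cells) and 18, 3, 1, 5 and 3 cells in naive 1, naive 2, metastasis 2, heterozygous and null. This class joins different clusters. All 194 cells lay in the monocyte or monocyte-derived macrophage cluster, which otherwise held 2 cells of naive 2. The remaining macrophage-like cells lay in the border-associated macrophage cluster. Endothelial-like cells numbered 13 in naive 2, 14 in the heterozygous and 4 in the null library, 2 in metastasis 1 and 0 in naive 1 and in metastasis 2. The exact upper limits of the shares in naive 1 and metastasis 2 were 0.920% and 4.74%. NK cell-like cells numbered 21 and dendritic cell-like cells 11 in metastasis 1, and at most 3 elsewhere. Clusters left unnamed took 2.26% of naive 1, 58.7% of metastasis 1, 18.1% of naive 2, 2.63% of metastasis 2, 13.9% of the heterozygous and 13.2% of the null library. In metastasis 1 they included 445 cells led by mt-Rnr1 and 58 cells led by Rhox5 and Esx1. The cluster led by mt-Rnr1 also had Top2a, Sdc1 and Mmp14 among its leading genes.

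The mean microglia-like share was 55.9% with metastasis and 81.0% in naive brains, a difference of −25.2 percentage points with an exact two-sided permutation p of 1 over the 4 libraries, where 0.333 is the smallest possible. Within replicate 1 the share was lower with metastasis and within replicate 2 it was higher. The Cd11b enrichment and the yield of kept cells can set these shares.

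**Figure D2:**
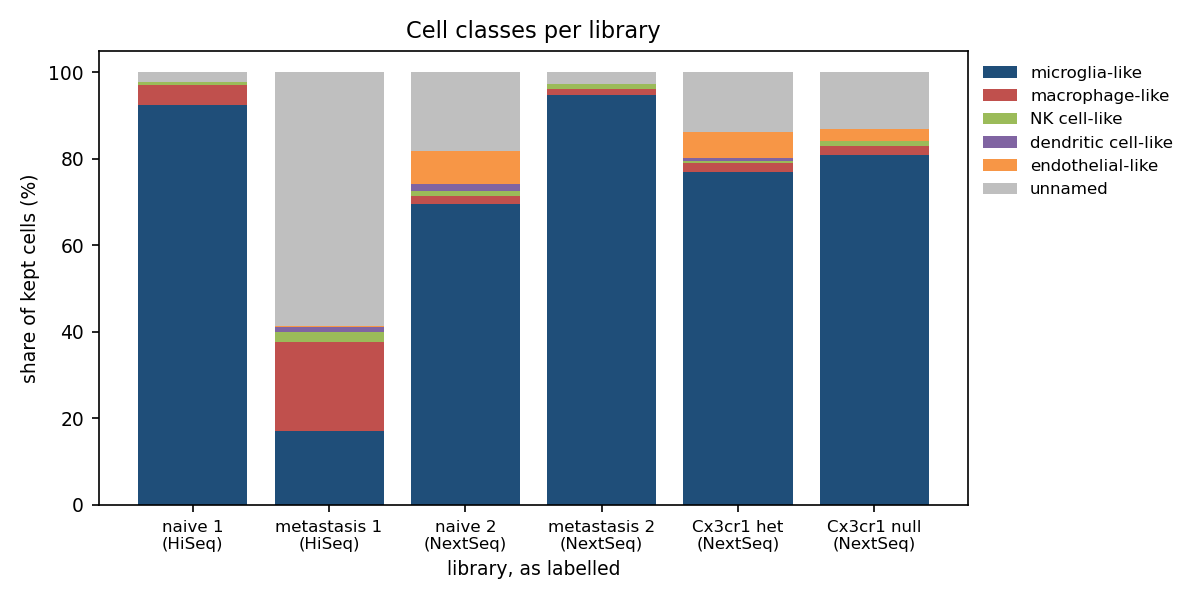
Share of kept cells in each class per library, in percent, as stacked bars that start at 0. Metastasis 1 holds 17.0% microglia-like and 20.6% macrophage-like cells, while microglia-like cells make up 69.6% to 94.7% of the other libraries.

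Within microglia-like cells the study asked how microglia respond to metastasis. Genes of resting microglia were lower as a group in metastasis with a preset correlation between genes, and not with an estimated one. All 16 tested members of the homeostatic list, among them Cst3 and Sparc, had fitted log2 changes below 0, with a median of −0.80, and the list fell by camera (adjusted p = 0.00139, but adjusted p = 0.859 with an estimated correlation). The lower levels were those of replicate 1, where nearly all microglia-like cells of metastasis 1 came from the cluster named only against its own library. Sparc, a matrix-associated glycoprotein of resting microglia, had a log2 ratio of −1.98 in replicate 1 and 0.41 in replicate 2. P2ry12, the purinergic receptor of resting microglia, had −2.56 and 0.93, and Tmem119 had −2.79 and 0.06, both named after their values were seen. The list median was −2.36 in replicate 1 (16 of 16 members lower) and 0.50 in replicate 2 (15 of 16 higher), and it was 0.16 without metastasis 1, in the opposite direction. Microglia markers that named the cells are in this list, and without them the adjusted p was 0.0516.

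The immediate-early and dissociation list, with transcription factors such as Fos, Jun and Egr1 that cell isolation can induce, also fell, with a median of −0.32 (camera adjusted p = 0.0292, but adjusted p = 0.859 with an estimated correlation). The median was −0.92 in replicate 1 and −0.16 in replicate 2, and 13 of 17 members had fitted changes below 0. The adjusted p was 0.245 without naive 1 and 0.691 without metastasis 1.

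The other 14 lists did not pass. The type I interferon list had a median of 1.58 in replicate 1 with 18 of 19 members higher, and −1.15 in replicate 2 with 18 of 19 lower (fitted median 0.15, camera adjusted p = 0.480). Ifitm3, a restriction factor against virus entry, had log2 ratios of 2.31 and −1.43 in the 2 replicates, and Slfn2 had 3.58 and −0.49. Chemokines had medians of 1.08 and −0.55, with Ccl4 at 0.68 and −0.34 and Ccl12 at 2.03 and −0.68. Matrix and remodelling genes had medians of 2.63 and −1.18, with the filament protein gene Vim at 5.37 and −1.67. Microglia-like cells of metastasis 1 also held leading transcripts of the unnamed Rhox5 cluster, chosen after their values were seen, with Rhox5 at 255 CPM against 0 UMIs in naive 1 and Wfdc2 at 83.9 against 1.48 CPM, so RNA from other cells is not excluded as a source of these ratios. Disease-associated genes had medians of 0.48 and −0.30, although the lipid carrier gene Apoe was above 0 in both, at 0.50 and 0.75. MHC class II genes were above 0 in both replicates, with medians of 0.49 and 0.30 and H2-Aa at 0.83 and 0.66, but the adjusted p was 0.399. Complement and Fc receptor genes were below 0 in both, at −0.95 and −0.20, with C1qa at −1.89 and −0.23 (adjusted p = 0.157).

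The remaining fitted medians were −0.28 for interferon gamma response (adjusted p = 0.480), 0.21 for inflammatory cytokines and NF-kB targets (0.480), −0.11 for MHC class I (0.932), −0.05 for immune checkpoints (0.649), 0.22 for lipid handling (0.399), −0.31 for lysosome and phagocytosis (0.190), 0.64 for matrix and remodelling (0.399), 0.20 for chemokines (0.480), −0.11 for disease-associated genes (0.756) and −0.25 for glycolysis and hypoxia (0.480). For proliferation the median was −0.16 while the mean was 0.16 and the test pointed up (0.519), but without a low-count filter its 20 genes had a median of 0.73 and passed (0.00379). These are camera adjusted p-values. No member of any list passed, over all genes or adjusted over the list alone.

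Gene by gene, 0 of 5371 genes passed in microglia-like cells (edgeR quasi-likelihood), with 181 at an unadjusted p under 0.05. DESeq2 called 2, which were chosen here after their values were seen. Ttr, a choroid plexus transcript, fell by 3.09 on the log2 scale (SE 0.517, DESeq2 adjusted p = 3.38e-05, 2 libraries per group) and was lower with metastasis in both replicates. Wfdc17 was higher in both, at 3.32 (SE 0.70, DESeq2 adjusted p = 0.0167). The other ependymal and choroid plexus markers, summed in microglia-like cells, stood at 81.4 CPM in naive 1 and 191 CPM in naive 2, against 13.4 CPM in metastasis 1 (4 UMIs) and 49.1 CPM in metastasis 2 (7 UMIs), so RNA from other cells is not excluded as the source of Ttr. Across genes, the log2 changes of the 2 replicates had a Pearson correlation of −0.19, and 45.4% of genes had the same sign. Genes are not independent replicates. Over all kept cells 0 of 7929 genes passed (147 at an unadjusted p under 0.05, DESeq2 0), with a correlation of −0.42 between replicates.

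The clusters behind the microglia-like class differed between libraries. In metastasis 1, 156 of the 160 cells were in a cluster led by Ccl4 and Gpr84 and named against the rest of that library, while naive 1 had 212 cells in a cluster led by casein genes and 126 in a cluster led by Otud1 and Egr1. Naive 2 had 93 of 119 cells in the cluster led by Ttr and Npl, and metastasis 2 had 42 of 72 in the casein-led cluster. The number of genes called without metastasis 2 was 314 and without naive 2 it was 18, against 0 with all 4 libraries.

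**Figure D3:**
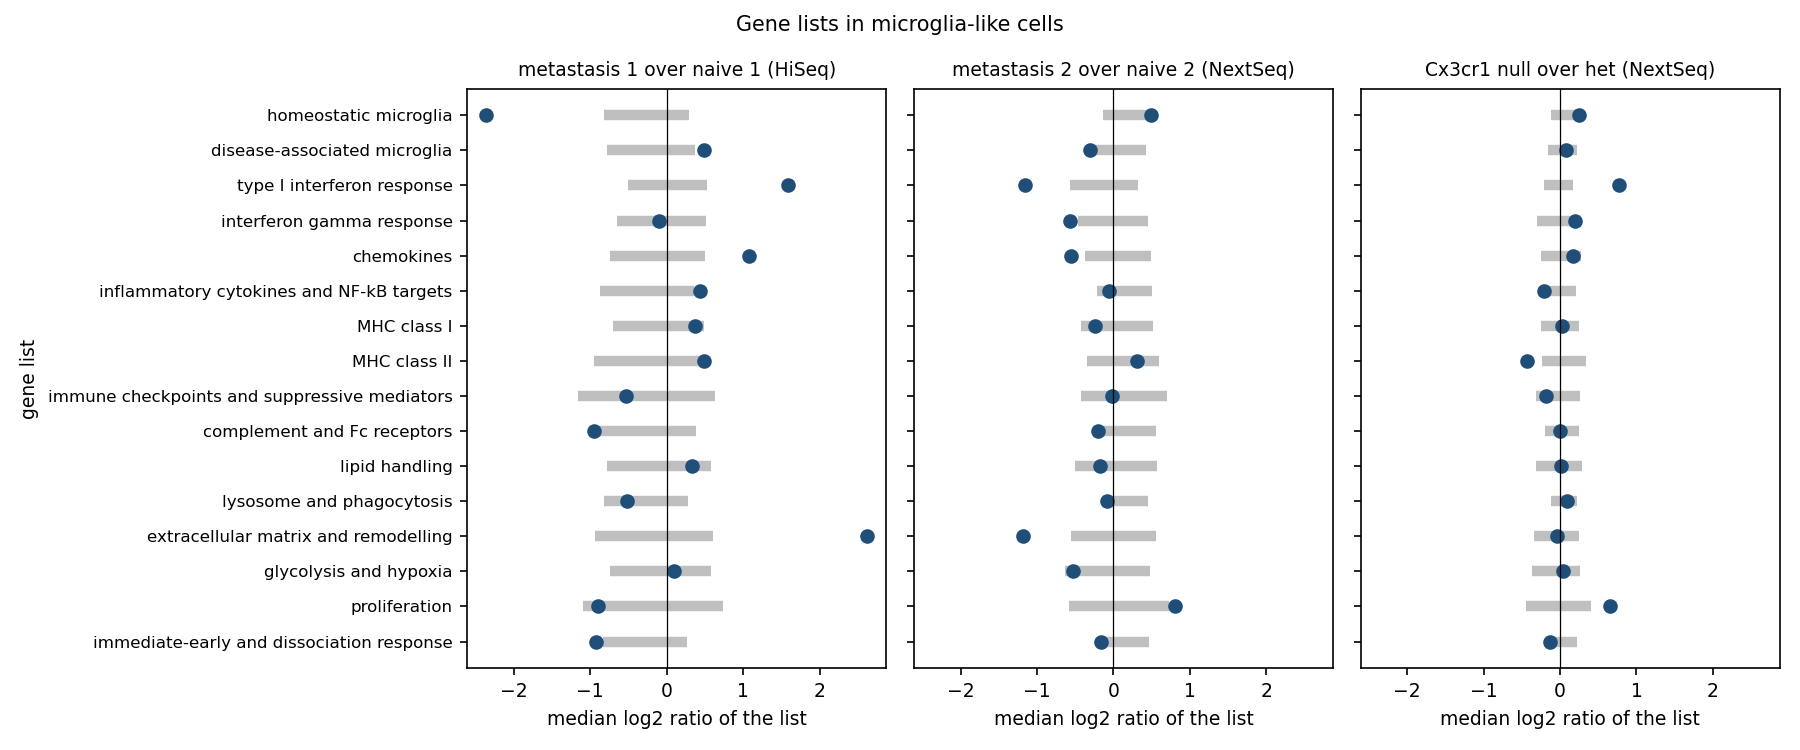
Median log2 ratio of each gene list in microglia-like cells within replicate 1, within replicate 2 and for null over heterozygous, on the same horizontal scale. Grey bars are the central 95% of 10000 matched random lists, and the homeostatic list lies at −2.36, 0.50 and 0.25 in the 3 panels.

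Loss of Cx3cr1 was examined by setting the null library beside the heterozygous one, both with metastases. Interferon-induced genes were higher in null microglia-like cells. Of 20 members of the type I interferon list, 19 had the higher level in the null library, with a median log2 ratio of 0.77 (0.48 to 0.85, counting error only), above all of the matched random lists. A UMI of the list was found in 121 of 123 null and 178 of 183 heterozygous cells. The 3 cells that held most had 28.2% of its UMIs in null and 21.5% in heterozygous. The interval does not cover this spread between cells. Oasl2, of the oligoadenylate synthetase family, had a log2 ratio of 1.90 (1.05 to 2.81). Ifitm3 was at 0.90 (0.59 to 1.22), Bst2, which tethers budding virus, at 0.56 (0.24 to 0.88) and Slfn2 at 0.29 (−0.10 to 0.67). The transcription factor Irf7, at 0.93 (0.35 to 1.51), was named after its value was seen. Lgals3bp was the member that was not higher, at −0.02. Libraries of a single label differed by more: the same list had a median of 1.63 for naive 2 over naive 1 and of −1.67 for metastasis 2 over metastasis 1. Each of these pairs spans both sequencers, while the null and heterozygous libraries share a sequencer. They therefore do not measure the spread between libraries of a single sequencer. Neutrophil markers were also higher in null, at 2413 CPM against 348 CPM over kept cells and at 1065 CPM against 537 CPM over all deposited barcodes. The unnamed cluster led by S100a8 and S100a9 held 3.95% of null cells (6 cells) and 4.62% of heterozygous cells (11 cells). RNA from other cells is not excluded.

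**Figure D4:**
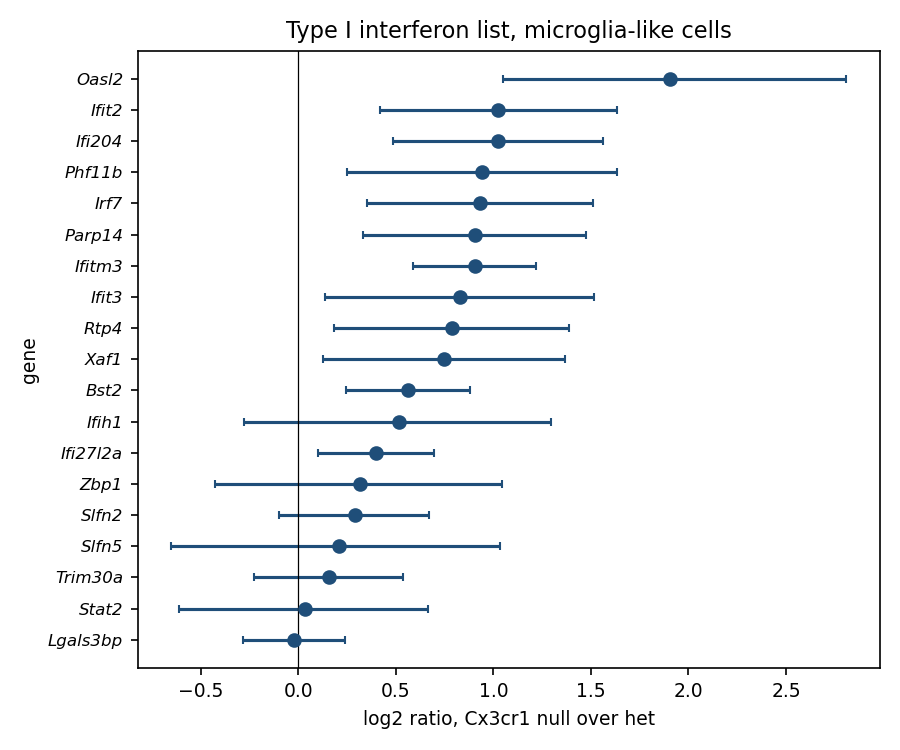
Log2 ratio of null over heterozygous CPM for 19 of the 20 measured members of the type I interferon list in microglia-like cells, with exact 95% counting intervals. Values run from −0.02 for Lgals3bp to 1.90 for Oasl2.

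Antigen presentation genes of MHC class II were lower in the null library, with a median of −0.44 (percentile 0.07 of random lists), 4 of 6 members lower and 2 higher, each with a counting interval that left out equality. H2-Aa was at −0.95 (−1.27 to −0.64), H2-Eb1 at −0.86 (−1.21 to −0.53) and Cd74, the invariant chain, at −0.64 (−0.85 to −0.42). Homeostatic genes had a median of 0.25 (percentile 98.9), with 14 of 16 higher, but lay inside the random range with a 25% mitochondrial limit (0.14, percentile 79.6), all deposited cells (0.14, percentile 88.3) and centring of each library (0.17, percentile 88.4). Cx3cr1 itself is a member of that list, and the mean was −0.01. The proliferation list, with 4 measured genes, had a median of 0.66 (percentile 99.9), with Pcna, the sliding clamp of DNA replication, at 0.99 (0.49 to 1.49). With a minimum of 20 UMIs its 9 genes had a median of 0.13 and a mean of −0.22, inside the random range (percentile 76.5). NF-kB targets were at −0.21 (percentile 2.34) and immediate-early genes at −0.13 (percentile 2.20). The first lay inside the range with the 25% limit (percentile 6.15) and with centring (percentile 22.4), and the second with 20 UMIs (percentile 3.22). For all 5 of these lists the median of metastasis 2 over metastasis 1 lay farther from 0, at −0.57 for MHC class II, 2.27 for homeostatic genes, 0.95 for proliferation, −0.81 for NF-kB targets and 0.38 for immediate-early genes. The medians of naive 2 over naive 1 were −0.01, −0.31, −0.22, −0.15 and −0.10 in that order, farther from 0 only for homeostatic genes. Both of these pairs span the sequencers, which the null and heterozygous libraries do not. The other 10 lists lay inside the central 95% of random lists, although interferon gamma response lay outside with the 25% limit (0.50, percentile 99.99), all kept cells (0.29, percentile 99.6) and all deposited cells (0.31, percentile 99.7), and chemokines over all kept cells and after thinning. Their medians were 0.19 for interferon gamma response, 0.17 for chemokines, 0.08 for disease-associated genes (mean −0.06), 0.02 for MHC class I (mean −0.02), −0.19 for immune checkpoints, −0.003 for complement and Fc receptors (mean 0.05), 0.02 for lipid handling (mean −0.09), 0.09 for lysosome, −0.04 for matrix genes and 0.04 for glycolysis. Within chemokines the members went both ways, with Ccl3 at −1.54 (−1.65 to −1.42), Ccl4 at −1.18 (−1.28 to −1.08) and Cxcl2 at 0.84 (0.32 to 1.36).

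Among single genes, the largest ratios higher in null were those of Oasl2, Rpl35, Dynll1, Dnajb1, Rps7, Lst1, Ift20 and Rps4x, from 1.90 to 1.44. Rpl35, Rps7, Lst1 and Rps4x lay below all libraries of unmodified mice in the heterozygous library and within their range in null. Oasl2 and Ift20 lay above that range in null only. Dynll1 lay above it in null and below it in heterozygous, and Dnajb1 lay inside it in both. Ribosomal protein genes such as Rpl35, Rps7 and Rps4x have near-identical copies, and their values are uncertain. The largest ratios lower in null were those of Apod (−5.90), Cx3cr1 (−4.53), Tagln (−4.27), Pik3ip1 (−3.50), Ptn (−3.40), Myl9 (−3.31), Npy and Fabp7. The last pair had 0 UMIs in the null library and log2 ratios of −3.72 and −3.47 with the floor of 3 counts. Their upper counting bounds were −3.39 and −3.12. A few heterozygous cells carried several of these transcripts: 3 cells held 91.3% of the Apod UMIs, 82.3% of Ptn, 85.1% of Myl9 and 76.4% of Tagln, 1 cell held all 74 Npy UMIs and 2 cells all of Fabp7. Pik3ip1 was spread over 72 of the 183 heterozygous cells and 6 of the 123 null cells. It stood at 163 CPM in the heterozygous and 14.4 CPM in the null library. In naive 1, metastasis 1, naive 2 and metastasis 2 it stood at 2.96, 30.2, 38.7 and 14.0 CPM. All of these lower genes except Cx3cr1 were above every library of unmodified mice in the heterozygous library. In the null library they lay within the range of unmodified mice, so the heterozygous library stood apart.

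Each genotype has 1 library, so these ratios compare libraries and not genotypes, with no replicate check. With thinned cells and the same UMI minimum, 3 chemokines had a median of −0.98 in place of 0.17 (0.52 over all kept cells, −0.05 after centring each library), and 4 type I interferon genes had 0.10 in place of 0.77, while the same 20 members without that minimum gave 0.84.

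Cxcl10, an interferon-induced chemokine on chromosome 5 at 92346638 to 92348889 (minus strand, mm10), was detected in similar shares of null and heterozygous microglia-like cells. After thinning to 800 UMIs, 7.69% of null cells (3.58 to 14.1, 9 of 117) and 7.43% of heterozygous cells (4.01 to 12.4, 13 of 175) had a UMI. The share was 13.8% in naive 1, 22.5% in metastasis 1 and 2.68% in naive 2. In metastasis 2 it was 0 of 48 cells, where the floor of 3 counts corresponds to a share of 6.25%. Thinning left out 80, 0, 7, 24, 8 and 6 cells in naive 1, metastasis 1, naive 2, metastasis 2, heterozygous and null. Cells of the other classes and clusters had a UMI in 25%, 20.4%, 10%, 25%, 12.7% and 13.8% of cells in that order, so in microglia-like cells only metastasis 1 exceeded them, by less than its counting error (16.3 to 29.8). In naive 1 and metastasis 2 these other cells were few, since 369 of 399 and 72 of 76 kept cells were microglia-like. These other cells had median depths of 4553 UMIs in the heterozygous and 4043 in the null library, against 3705 and 3086 in microglia-like cells. They include monocyte- and macrophage-like cells, which can express Cxcl10, so no class certain to lack it was at hand. The shares are not read as expression above background. Without thinning the shares were 22.0%, 40.6%, 13.4%, 2.78%, 25.1% and 26.0%.

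The Cxcl10 level was 256 CPM in the null and 147 CPM in the heterozygous library, a log2 ratio of 0.80 (0.41 to 1.19). Of the 107 null UMIs, 61 lay in 2 cells, and the ratio was −0.18 after thinning, so no difference is read from it.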

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

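The test of a wrong label in replicate 2 was written before its result was seen, and the other tests in this part were chosen afterwards. The casein test was first run over naive 1 and metastasis 2 together, decided nothing and was then split by library with new criteria.

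Between metastasis and naive microglia-like cells, 5 gene lists moved in opposite directions in the 2 replicates, with both medians outside the central 95% of random lists, a limit set after the values were seen. The medians of replicate 1 minus replicate 2 were −2.86 for homeostatic genes, 0.78 for disease-associated genes, 2.74 for type I interferon response, 1.63 for chemokines and 3.80 for matrix and remodelling genes. These differences were not tested, since each replicate has 1 library per group. By arithmetic, exchanging the labels of replicate 2 would give each of the 5 lists the same sign in both replicates, and following the names of the deposited tables in both replicates would reverse every direction between metastasis and naive.

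The labels and the names of the deposited tables give opposite groups for the 4 libraries of unmodified mice. A wrong label in replicate 2 predicts that naive 2 lies nearer than metastasis 2 to the heterozygous and null metastasis libraries, and over all cells its Spearman correlation across genes was higher by 0.0957 and 0.0855. Depth as the whole cause is argued against, because at 151447 UMIs per library the smaller difference was still 0.0295 and never below 0.0219 in 20 draws, and the 58 cells of the Rhox5 cluster in metastasis 1 and 0 in naive 1 would argue against a wrong label in replicate 1 only if these are carcinoma cells, while metastasis 2, the heterozygous and the null library held 0, 0 and 1 of this cluster. At 151447 UMIs per library, the mean correlation with naive 1 was 0.808 for metastasis 2 and 0.719 for naive 2. With metastasis 1 it was 0.579 for metastasis 2 and 0.643 for naive 2. These libraries also differed in their mix of cell classes, so the values do not decide between the explanations. A preparation batch stays open, since the median mitochondrial share was 19.3% in naive 2, 20.3% in the heterozygous and 19.4% in the null library but 3.60% in metastasis 2. Both a wrong label and such a batch may therefore lie behind the nearness of naive 2 to the heterozygous and null libraries. The opposite names do not decide between them. A batch would not account for the names, and neither would a wrong label in replicate 2 alone, since they are opposite in both replicates. A true difference between these animals was not tested.

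The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. Over all cells, 0 of 7929 genes passed with the labelled groups and 70 with replicate 2 exchanged, the highest of the other splits (edgeR, 147 at an unadjusted p under 0.05 as labelled, DESeq2 0). This points to a structure over all cells that the labelled groups do not follow. That split sets naive 1 and metastasis 2, with 92.5% and 94.7% microglia-like cells, against metastasis 1 and naive 2, with 17.0% and 69.6%. The mix of cell classes is therefore not excluded as the source of the 70 genes. In microglia-like cells 0 genes passed in each of the 3 splits, with 181 at an unadjusted p under 0.05 as labelled and 349 with replicate 2 exchanged (edgeR, DESeq2 called 2 genes as labelled).

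Casein transcripts, which encode milk proteins, stood at 1129 CPM over the deposited barcodes of naive 1 and at 128 CPM in metastasis 2. They were at 23.6 CPM in metastasis 1, which was sequenced like naive 1, and at 1.85 CPM in naive 2, which was sequenced like metastasis 2, and this argues against the sequencing batch as the source. In naive 1 caseins were 3.36 times as frequent in the shallower as in the deeper barcodes and reached 521 of 1000 barcodes, so free RNA from cells outside the barcodes may be their source there. In metastasis 2, 65.1% of the casein UMIs lay in 5 barcodes, which argues against evenly spread free RNA. No biological explanation was tested.

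Type I interferon genes were higher in null than in heterozygous microglia-like cells, with a median log2 ratio of 0.77. The same 20 members had a median of 0.84 (0.39 to 1.12) after each cell was thinned. This does not exclude depth, because counts under 3 were set to 3 in both libraries. With 117 null and 175 heterozygous cells at that depth, this raises the ratio of members at the floor. The members that kept the UMI minimum after thinning had a far lower median, given above. A different mix of clusters is argued against, since the median was 0.80 (0.51 to 0.89) within the cluster that holds most null cells. RNA from other cells cannot be told apart, because the excess in microglia-like cells less that in barcodes removed for their mitochondrial share was −114 CPM (−364 to 137), an interval that holds 0. The genotype may play a part, as a hypothesis that a single library per group leaves untested. Libraries of a single label, which also differ in sequencer, differed by 1.63 and −1.67.

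A cluster of cells led by Rhox5 and Esx1, which was given no class name, had 58 cells in metastasis 1, 1 in the null library and 0 in each of the others.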

How the results depend on the processing

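Alternatives that used a 25% mitochondrial limit, 200 genes per cell, crossed pairs, the class without its within-library or casein-led clusters, all deposited cells for gene lists and Cx3cr1, or centring for class shares and null over heterozygous were chosen after the data were seen. In microglia-like cells, where 0 genes passed, DESeq2 called 2, no low-count filter 57, all deposited cells 6, coarser clusters 4, the 25% mitochondrial limit 1 and the class without within-library clusters 4, although only 4 cells of metastasis 1 were then left. Leaving out single libraries gave 0 to 314 genes: 0 without naive 1, 2 without metastasis 1, 18 without naive 2 and 314 without metastasis 2. Over all cells, where 0 genes passed, the same gave 0 to 42: 42 without naive 1, 10 without naive 2, 0 without either metastasis library. With 1 library in a group, it is assumed to vary like the other group. The replicate block changed no call. Crossed pairs gave 0 genes in microglia-like and 2 over all cells. The other alternatives gave 0.

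The number of lists past the threshold, 2 as reported, was 0 with an estimated correlation, 0 with fry, 2 with the block, 2 with RLE size factors, 3 without a low-count filter (proliferation was added, with a median of 0.73 in place of −0.16), 0 without microglia markers, 0 without within-library clusters, 0 with all deposited cells, 1 without the casein-led cluster and 8 over all cells. It was 1 to 10 when single libraries were left out, with 1 without naive 1, 2 without metastasis 1, 4 without naive 2 and 10 without metastasis 2. The homeostatic median ranged from −1.93 without metastasis 2 to 0.16 without metastasis 1, where its direction reversed. Type I interferon response ranged from −0.94 without metastasis 1 to 0.89 without metastasis 2, and chemokines likewise from −0.58 to 1.33. Over all cells the medians of type I interferon response and MHC class II reversed to −0.78 and −1.17. The Cxcl10 ratio of null over heterozygous reversed to −0.18 after thinning. Apart from the fewer libraries or cells named, the cause was not tested.

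Of 1121 values of genes under alternatives of metastasis against naive, over 59 genes, 146 (13%) changed sign, all of them short of the threshold in both settings. Of per-library values, 18 of 36 microglia-like shares, 12 of 36 macrophage-like shares, 8 of 18 Cx3cr1 levels and 10 of 18 Cxcl10 shares moved beyond their counting intervals. The summaries over libraries (the difference in microglia-like share, −25.2 points, between −33.2 and −5.5 under alternatives, and the null over heterozygous Cx3cr1 ratio, −4.54 to −4.38) were defined after the data were seen and are judged against a wide spread. Lists outside the random range for null over heterozygous numbered 6, and 4 to 8 under alternatives. Macrophage-like cells were not compared because naive 1, naive 2 and metastasis 2 had 18, 3 and 1, so the alternatives planned for them were not run. Depth limits metastasis 2 most, with 72 microglia-like cells and 142440 UMIs.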

Other observations

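The comparisons in this part were chosen after the data were seen.

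Beside naive 2, which was sequenced on the same instrument, microglia-like cells of the Cx3cr1 genotypes had higher MHC class II medians, at a log2 ratio of 1.24 for the heterozygous and 0.70 for the null library. The type I interferon medians over naive 2 were 0.41 and 0.93. Homeostatic genes were at 0.04 and 0.22, and chemokines at 0.17 and 0.35. Each of these compares single libraries, and the label of naive 2 is in doubt.

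The Rhox5 cluster held more of a pair of epithelial transcripts from the carcinoma marker list than the rest of metastasis 1. Krt8, a keratin, stood at 202 CPM against 44.8 CPM, and Wfdc2 at 329 CPM against 89.6 CPM. That rest includes the 445 cells of the cluster led by mt-Rnr1. With all deposited cells, a cluster led by mt-Rnr1 with 668 cells of metastasis 1 had Rhox5 among its leading genes. Epcam was at 4.55 and 1.66 CPM, Cdh1 at 3.03 and 8.30 CPM and Krt18 at 0 and 0.55 CPM. Over kept cells, Krt8 had 213 UMIs in metastasis 1, 7 in naive 1, 11 in the heterozygous, 2 in the null library and 0 in naive 2 and metastasis 2. Members of the list went both ways between metastasis 1 and naive 1. Wfdc2 had 379 and 1 UMIs and Cdh1 17 and 0, but Epcam had 6 and 19 and Krt18 had 1 and 8. Lcn2, a member of both the carcinoma and the neutrophil list, had 493 UMIs in naive 2 and at most 35 in any other library. It also stood among the leading genes of the endothelial-like cluster, which held 13 cells of naive 2 and 14 of the heterozygous library.

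Markers of classes that named no cluster were summed per library over kept cells. Neutrophil markers reached 2413 CPM in the null and 348 CPM in the heterozygous library (1065 and 537 CPM over all deposited barcodes). Carcinoma markers reached 730 CPM in naive 2, 266 CPM in metastasis 1, 92.7 CPM in naive 1, 66.2 CPM in the null, 32.6 CPM in the heterozygous library and 0 in metastasis 2. Without Lcn2 the carcinoma sums were 20.2 CPM in naive 2, 251 in metastasis 1, 51.5 in naive 1, 3.68 in the null and 17.2 in the heterozygous library. Ependymal or choroid plexus markers ranged from 184 to 1444 CPM, mural from 1.29 to 782, B cell from 31.3 to 366, astrocyte from 92.4 to 301, oligodendrocyte lineage from 71.5 to 195, erythroid from 11.0 to 148, T cell from 6.60 to 97.9 and neuron from 9.19 to 33.0.

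Cxcl10 in barcodes removed for their mitochondrial share was at 340 CPM (307 to 376) in the null and 135 CPM (114 to 158) in the heterozygous library. It was at 256 and 147 CPM in microglia-like cells.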
